A study of Mus musculus with 10 samples.

How the data were processed

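RNA was sequenced from mouse embryonic stem cells (ESCs) of the line V6.5 and from cells made from them by neural differentiation, which the labels call NPCs (neural progenitor cells) and which are named here by that label. Per the labels' protocols, ESCs grew on irradiated mouse fibroblast feeders with leukemia inhibitory factor, embryoid bodies were formed for 4 days, dissociated and plated in ITSF medium, siRNA was transfected on day 5 and RNA was taken on day 8. Cells received a control siRNA against luciferase, a siRNA against Cbx3 or, at the NPC stage, a siRNA against Med26. The 10 libraries form 5 groups of 2, and the labels number the replicates 1 and 2 in each group and call them biological. RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols. The sequences of the siRNAs are not given in the sources used here.

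The deposited table gives RPKM values, reads per kilobase of transcript per M mapped reads (M stands for mega), which the authors computed for each RefSeq transcript accession in each library. TopHat2 2.08 and the mouse build mm9 are named in the submitters' processing notes. The counting tool, the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. Isoforms, overlapping genes and near-identical copies of a gene can therefore share reads, and named genes with named pseudogene copies are pointed out in the text. The table has 35860 rows with 34720 different accessions, and 99.07% of rows were given a gene symbol through the RefSeq gene table of GRCm38.p6, used for names only, with 334 rows left unmatched. Where a gene had several rows, the row with the highest mean RPKM over all libraries stood for it, which gave 24520 genes and applied to 3764 of those tested. No coordinates are printed, since no mm9 genome or annotation was used here.

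RPKM values are not counts, and no count test was run. The depth of each library was estimated from its low values. RPKM multiplied by transcript length, up to 0.3, fell on steps, and 64.5% to 69.6% of values lay within 0.1 reads of a whole number of steps, too few to recover whole reads. The steps correspond to 51.3 M and 24.0 M reads in ESC control replicates 1 and 2, 33.6 M and 23.3 M in ESC Cbx3 siRNA, 53.8 M and 55.0 M in NPC control, 45.7 M and 46.9 M in NPC Cbx3 siRNA, and 54.8 M and 63.8 M in NPC Med26 siRNA. A gene of 1 kilobase at 1 RPKM thus rests on 23.3 to 63.8 reads. How many fragments these reads stand for is not given in the sources used here, so counting error was not ranked by them.

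Genes with at least 1 RPKM in at least 2 of the 10 libraries were tested (11956 genes). log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. All 10 libraries entered 1 fit without a block, a design chosen before the data were examined. A fit of the libraries of 1 cell type and a fit with the replicate number within each cell type as a block were planned as alternatives. After the data were examined, the fit of the 6 NPC libraries was taken as the basis for describing genes and lists in NPCs, because the ESC replicates differed far more from each other than the NPC replicates. In the text, NPC genes and lists "rose" or "fell" when they passed the threshold in the fit of the 6 NPC libraries, and the counts of the 10-library fit are given beside them. The difference between NPC and ESC control comes from the fit of all 10 libraries. With 2 libraries per group, the residual degrees of freedom were 5 for the 10 libraries, 3 for the NPC libraries and 3 for the fit with the block.

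Before the data were examined, 33 gene lists were written from general knowledge, 19 by process and 14 by cell type, including the feeder fibroblasts and other cell types that a culture could hold. The 31 lists with at least 5 tested members were tested with fry (limma), which asks whether members move, on balance, in 1 direction, and adjusted over the lists. The lists were heterochromatin, Mediator, transcription elongation, histone genes, cell cycle, p53 targets, apoptosis, interferon response, integrated stress response, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early, Notch pathway, Wnt targets, TGF-beta and BMP targets, extracellular matrix, pluripotency, neural progenitor, neuron, glia, mesoderm, muscle, endoderm, epidermis and epithelium, neural crest, fibroblast feeder, blood and endothelium, trophoblast and germline. Hox genes (2 tested members of 35) and genes of 2-cell-like cells (0 of 17) were too few. camera was run with a preset and with an estimated correlation between genes. With the estimated correlation, no list passed in any of the 3 knockdown comparisons under the 10-library fit, the NPC fit or the fit with the block.

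The genes named in the text follow a rule written before the data were examined. Cbx3, Med26, Cbx1, Cbx5, Pax6, Sox1, Nes, Neurog2, Tubb3, Pou5f1, Nanog, T, Gata4, Gata6, Sox17 and Acta2 were always named. For each knockdown comparison the rule adds the 8 largest rises and the 8 largest falls among genes past the threshold whose higher group had a mean of at least 5 RPKM and whose libraries did not overlap between groups, and the 3 called members with the smallest p of each list with at least 3 called members. For the other comparisons it adds the 5 largest in each direction. Predicted genes and small RNA genes were skipped. The rule for the knockdown comparisons was applied to the genes called in the 6 NPC libraries, and in ESCs, where the 10-library fit called none, to those called with the block. Some genes that meet the rule are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

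Alternatives were other pseudocounts, no filter and a filter at 5 RPKM, median-ratio scaling, quantile normalization, limma without a trend or with robust moderation, a 2-fold minimum, leaving out each library in turn, the replicate block, the libraries of 1 cell type, and, added after the data were examined, leaving out genes with named pseudogene copies and genes that carry a 7-base sequence. For a named gene, a change of sign was counted as a reversal only where a value on either side passed the threshold. Overlaps of calls are given beside the number expected of independent lists, and comparisons that share the NPC control libraries beside 100 simulations of unchanged groups against those controls. Named pseudogenes, transcript length, GC content and 3' UTR sequences were taken from GENCODE vM21, with a RefSeq to GENCODE match, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

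The tests were checked on simulated values for 11956 genes, with 200 changed genes in each of 10 runs. Each gene had 1 spread, taken from the fit and the same in all its libraries. The real ESC replicates differed more than the NPC replicates, so the rates of the 10-library fit need not hold for these data. For Cbx3 siRNA in NPCs, the fit of the NPC libraries called 91% of genes changed 1.5-fold, 99.4% of those changed 2-fold and 99.8% of those changed 3-fold, and 0.112% of unchanged genes. The 10-library fit called 18.4%, 70.9% and 92.6%, and 0.0537% of unchanged genes. For Cbx3 siRNA in ESCs, the fit with the block called 98.7%, 100% and 100%, and 0.126%. A list of 20 genes shifted by 0.3 log2 units was found in 10 of 10 runs by the fit of the NPC libraries and by the fit with the block and in 8 of 10 by the 10-library fit, with 0 of 300 unshifted lists called. Genes were drawn independently of each other, so these runs could not show false calls of lists whose genes vary together. A 7-base sequence given a shift of 0.08 in 11017 genes ranked first in 10 of 10 runs.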

Results

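Cbx3 encodes HP1 gamma, a chromodomain protein of heterochromatin and of transcribed genes, and Med26 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. The title of the series names Cbx3 as a keeper of lineage choice while mouse embryonic stem cells (ESCs) turn toward neural cells. ESCs received a control siRNA or a siRNA against Cbx3. Cells on the way to the neural fate, labelled NPCs, received a control siRNA, a siRNA against Cbx3 or a siRNA against Med26 on day 5, and their RNA was taken 3 days later. Each of the 5 groups had 2 libraries, and 11956 genes were tested. With n = 2 per group, the p-values measure only the spread between these samples.

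Each siRNA lowered its target in every library that received it. Cbx3 RNA was 9.37 and 9.65 RPKM in NPC control and 0.425 and 0.248 RPKM after Cbx3 siRNA. The log2 change was -2.98 (standard error 0.09, adjusted p = 0.000171 in the fit of the 6 NPC libraries), and it did not pass in the fit of all 10 libraries. Med26 siRNA left Cbx3 at 7.87 and 7.93 RPKM. In ESCs Cbx3 was 13.99 and 56.4 RPKM in control and 1.007 and 1.96 RPKM after Cbx3 siRNA, a log2 change of -3.59 that did not pass (standard error 0.53, adjusted p = 0.291 in the fit of all 10 libraries). The ESC control libraries lay 1.94 log2 units apart, and Cbx3 has 8 named pseudogene copies whose reads can be counted with it. Med26 RNA was 7.56 and 6.78 RPKM in NPC control and 3.04 and 3.07 RPKM after Med26 siRNA, a log2 change of -1.01 (standard error 0.10, adjusted p = 0.0218 in the fit of all 10 libraries). It did not pass there without any 1 of the 6 NPC libraries (adjusted p from 0.0639 to 0.3671), and it passed in the fit of the 6 NPC libraries (adjusted p = 0.00398). After Cbx3 siRNA Med26 was 7.42 and 6.35 RPKM in NPCs and 5.61 and 5.78 RPKM in ESCs, against 6.02 and 6.01 RPKM in ESC control. The other HP1 genes, Cbx1 (log2 change -0.15, adjusted p = 0.105) and Cbx5 (0.13, adjusted p = 0.143), did not pass after Cbx3 siRNA in NPCs.

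**Figure D1:**
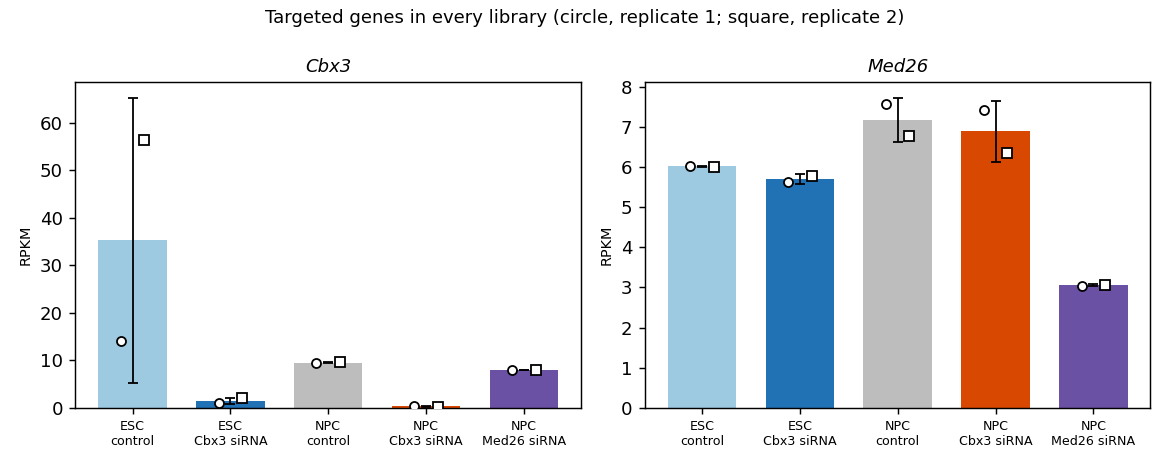
RPKM of Cbx3 and Med26 in each of the 5 groups. Bars are means, error bars are SD and points are the 2 libraries of each group.

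Cell type set the libraries apart first. The first principal component held 55.4% of the variance and separated ESC from NPC libraries. The second held 25.7% and separated ESC replicate 1 from ESC replicate 2 in both siRNA groups. Replicates correlated at r = 0.949 in both ESC groups and at 0.995 or 0.996 in the NPC groups. The spread of the ESC replicates entered the error of every gene when all 10 libraries were fitted together. The median residual SD was 0.156 in that fit and 0.083 in the 6 NPC libraries. The ESC Cbx3 siRNA library of replicate 1 also held 13661.7 RPKM of the ribosomal RNA precursor Rn45s, against 4019.9 to 5730.3 RPKM in the other 9.

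**Figure D2:**
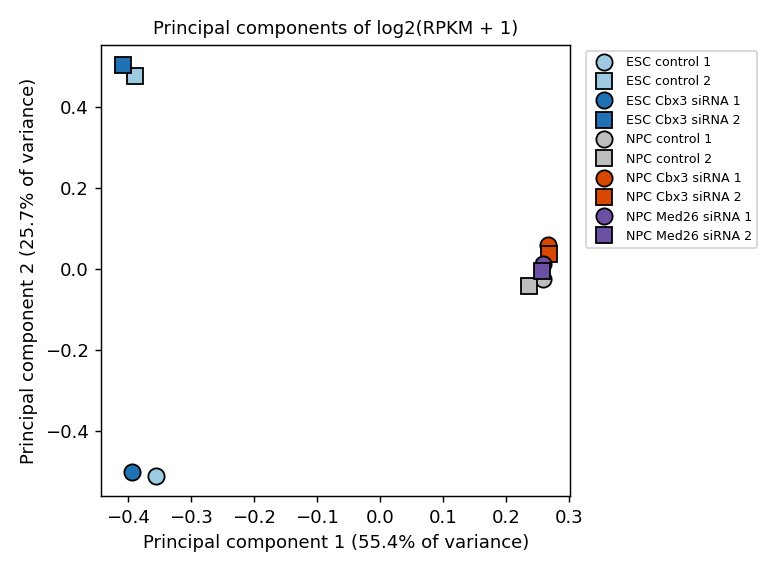
The 10 libraries on the first and second principal components of log2(RPKM + 1). Axes give the percentage of variance.

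NPC control had less Esrrb, Nr0b1 and Klf4 than ESC control but had not lost Pou5f1. Esrrb fell from 33.5 RPKM in ESC control to 1.04 RPKM in NPC control (log2 change -3.79, adjusted p = 0.0121), with Nr0b1 (-3.75, adjusted p = 0.00329) and Klf4 (-3.18, adjusted p = 0.0132), all factors of the naive pluripotent network. Pou5f1, the central pluripotency factor, stayed at 491 ± 9.3 RPKM in NPC control against 422 ± 160 RPKM in ESC control (mean ± SD, n = 2, adjusted p = 0.553), and Nanog did not pass either (-0.24, adjusted p = 0.77). Nes rose from 10.9 ± 6.4 to 34.2 ± 1.0 RPKM (1.68, adjusted p = 0.0448) and Sox1 from 5.51 to 8.76 RPKM (0.58, adjusted p = 0.0103), Pax6 did not pass (0.95, adjusted p = 0.0534), and Tubb3 did not pass (0.27, adjusted p = 0.316). Sox2 fell (-1.68, adjusted p = 0.014). The primitive streak genes T (1.44, adjusted p = 0.00274) and Fgf8 (0.137 to 4.64 RPKM, adjusted p = 0.00124) rose, with the muscle genes Actc1 (3.18, adjusted p = 0.00592) and Cnn1 (3.04, adjusted p = 0.0162), the transmembrane gene Prom1 (2.55, adjusted p = 0.0149), Ppp4r4 (2.80, adjusted p = 0.0138) and Enpp2 (2.64, adjusted p = 0.00728). Acta2 fell (-0.69, adjusted p = 0.0247), as did Mymx (-3.78, adjusted p = 0.00676). The fibroblast gene S100a4 fell as well (-3.81, adjusted p = 4.24e-05), and the ESCs had grown on fibroblast feeders. Neurog2 stayed at or below 0.0658 RPKM, Sox17 at or below 0.374 RPKM and Gata6 at or below 1.13 RPKM in every library, and these were not tested. Gata4 did not pass (0.37, adjusted p = 0.34).

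Between the control groups 1918 genes passed, 1208 higher and 710 lower in NPCs, in the fit of all 10 libraries. The neural progenitor list rose (9 of 24 members higher and 3 lower, or 13 and 3 adjusted over the list alone, adjusted p = 0.00298, and adjusted p = 0.498 with an estimated correlation) and the pluripotency list fell (2 higher and 13 lower of 30, or 3 and 18, adjusted p = 0.00257, and adjusted p = 0.275 with an estimated correlation). The fibroblast feeder list fell (0 higher and 9 lower of 23, or 1 and 12, adjusted p = 0.00897, and adjusted p = 0.498 with an estimated correlation). In all, 14 of the 31 lists passed with fry, and none with an estimated correlation between genes. The number of genes fell to 185 or 240 without NPC control replicate 1 or 2, to 1113 without either NPC Cbx3 siRNA library, to 1087 without either NPC Med26 siRNA library and to 1187 without ESC control replicate 1.

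Cbx3 siRNA in NPCs raised Krt8, Krt18 and Acta2 and lowered Pax6, Sox1 and Sox2. Krt8, a keratin of simple epithelia, rose from 61.0 ± 2.3 to 176 ± 10 RPKM (log2 change 1.51, standard error 0.06, adjusted p = 0.000285, mean ± SD of n = 2 per group). Its partner Krt18 rose from 136 ± 6.4 to 314 ± 16 RPKM (1.20, adjusted p = 0.000731). Smooth muscle actin, Acta2, rose from 18.6 to 43.4 RPKM (1.18, adjusted p = 0.000408). Pax6, a member of the neural progenitor list, fell from 3.41 to 1.24 RPKM (-0.98, standard error 0.08, adjusted p = 0.00226). Sox1 fell from 8.76 ± 0.66 to 4.97 ± 0.37 RPKM (-0.71, adjusted p = 0.00639), Sox2 from 29.8 to 20.03 RPKM (-0.55, adjusted p = 0.00541) and the Notch ligand Dll1 from 2.17 to 0.944 RPKM (-0.71, adjusted p = 0.00607). Nes did not pass (-0.14, adjusted p = 0.155), and the neuronal genes Tubb3 (-0.39, adjusted p = 0.0242), Elavl2 (-0.47, adjusted p = 0.0199) and Neurod1 (-0.44, adjusted p = 0.0273) fell. These changes are on the scale of log2(RPKM + 1), which understates those of low genes such as Pax6 and Dll1.

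**Figure D3:**
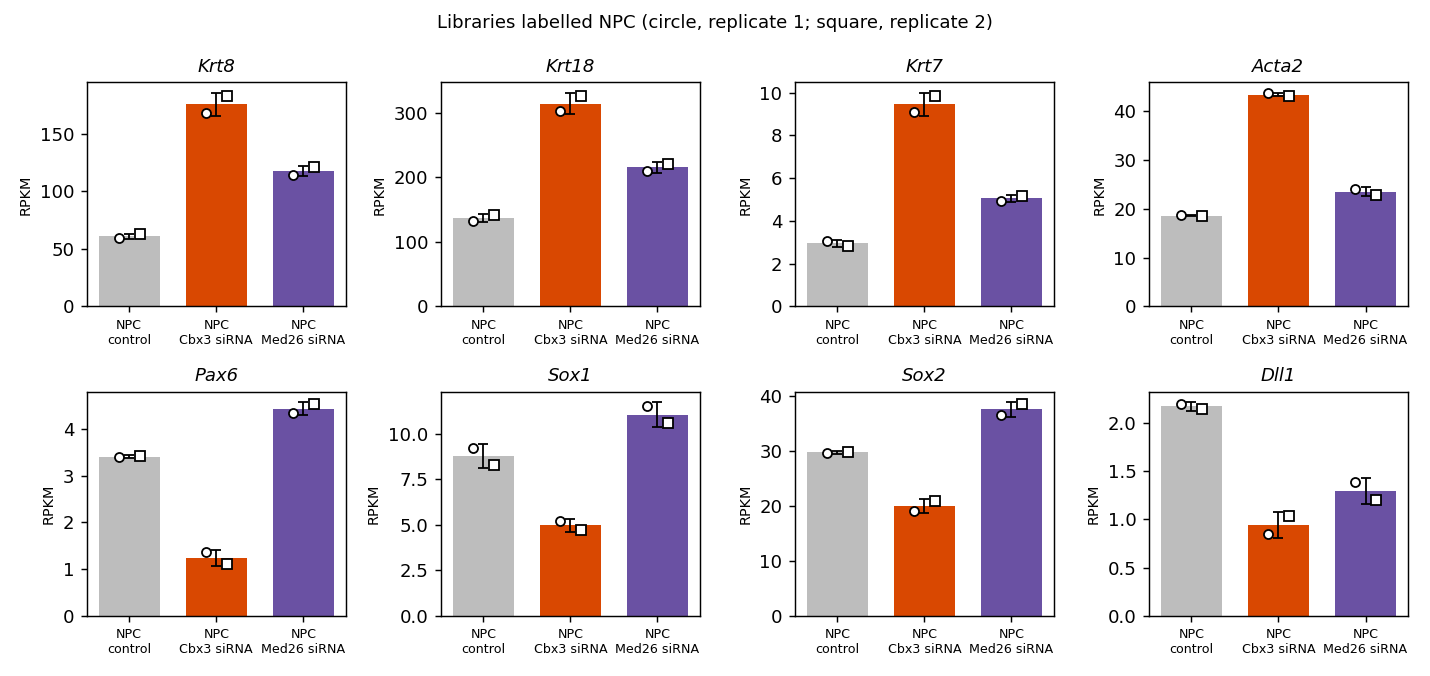
RPKM of Krt8, Krt18, Krt7, Acta2, Pax6, Sox1, Sox2 and Dll1 in the 3 NPC groups. Bars are means, error bars are SD and points are the 2 libraries of each group.

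Among the largest rises after Cbx3 siRNA, beside Krt8, were Car2 (66.4 to 199 RPKM, log2 change 1.57), Rassf1 (1.56), Tinagl1 (1.54), the cornified envelope enzyme Tgm1 (6.05 to 18.9 RPKM), Stmn4 (1.49) and the calcium binder S100a6 (33.5 to 90.6 RPKM, 1.41), with adjusted p from 0.000171 to 0.00299. Krt7 rose too (1.41, adjusted p = 0.000808). The largest falls, beside Cbx3 and Pax6, were the thyrotropin-releasing hormone gene Trh (52.97 ± 3.6 to 12.8 ± 0.12 RPKM, -1.97, adjusted p = 0.000175), the H3 methyltransferase Ehmt2 (31.3 to 10.2 RPKM, -1.53, adjusted p = 0.000175), Erlin2 (-1.30), Rptor (-1.02), Enpp2 (-0.98), Pdk1 (-0.94) and Ccnd2 (-0.93). The de novo DNA methyltransferase Dnmt3b fell from 348 to 205 RPKM (-0.76, adjusted p = 0.00161). Of the 16021 sequences of 7 bases searched in 3' UTRs, GAGAGTT ranked lowest by the weaker of its z values in NPCs and ESCs. It is weighed below as a possible off-target match of the Cbx3 siRNA. The transcripts of Ehmt2, Erlin2, Rptor, Elavl2, Trp53inp1 and Pfkl carry GAGAGTT, and those of Pax6, Sox1, Sox2, Dll1, Krt8 and Krt18 do not. Transcripts of some genes that rose, Acta2, Tgm1, Col5a1 and Spp1, carry it too. Of the genes searched, 35.3% of those that fell (213 of 603), 10.8% of those that rose (96 of 889) and 18.8% of the others carry it in the transcript. The sequence was picked from these same changes, so a higher share among genes that fell follows in part from that choice. Over all genes searched, those with the sequence in the 3' UTR lay lower after this siRNA in NPCs (z = -15.09) and in ESCs (z = -15.42). Nanog has 2 named pseudogene copies, and Krt8 and Phgdh have 1 each. Pou5f1 (491 to 392 RPKM, -0.32, adjusted p = 0.0247) and Nanog (-0.30, adjusted p = 0.0326) fell slightly. T (0.38, adjusted p = 0.0837) and Gata4 (0.21, adjusted p = 0.357) did not pass.

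In the 6 NPC libraries 1570 genes passed after Cbx3 siRNA, 933 higher and 637 lower, of which 58 changed at least 2-fold, 52 of them upward. The fit of all 10 libraries, chosen before the data were examined, called 1 gene, Ier3 (log2 change 1.03, adjusted p = 0.0371). It counted 1319 genes at unadjusted p under 0.05. The number in the 6 NPC libraries fell to 390 and 481 without NPC control replicate 1 and 2, to 474 and 488 without NPC Cbx3 siRNA replicate 1 and 2, and to 1066 and 1062 without Med26 siRNA replicate 1 and 2 (limma). Of the 66 genes named for this comparison, 47 to 64 still passed.

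Of the 31 gene lists, 15 moved by fry in the 6 NPC libraries after Cbx3 siRNA. With an estimated correlation between genes no list passed. Adjusted p was then 0.149 for epithelium, cholesterol synthesis, interferon, trophoblast, feeder and neural progenitor lists, 0.187 for heterochromatin, 0.212 for muscle, TGF-beta and p53 lists and 0.286 to 0.404 for the other 5. The list of epidermis and epithelium rose (11 higher and 0 lower of 24, or 13 and 0 adjusted over the list alone, adjusted p = 0.000287), as did cholesterol synthesis with Insig1 (0.67) and Lss (0.66) (10 and 1 of 28, or 12 and 1, adjusted p = 0.000287). The interferon response rose with Cxcl10 (1.46), H2-D1 (0.70) and B2m (0.41) (11 and 1 of 18, both ways, adjusted p = 0.00042). Trophoblast genes, which share Krt8 and Krt18 with the epithelial list and include H19 (1.11), rose (7 and 0 of 10, or 7 and 1, adjusted p = 0.000857). So did fibroblast feeder genes with Thbs1 (0.79), Col5a1 (0.70) and Col6a2 (0.61) (8 and 1 of 23, both ways, adjusted p = 0.00414). Muscle genes with Acta1 (0.43) and Myh6 (0.51) rose (6 and 0 of 16, both ways, adjusted p = 0.00449), as did mesoderm genes with Wnt3 (0.40) (2 and 0 of 10, both ways, adjusted p = 0.00414). TGF-beta and BMP targets rose with Lefty2 (0.84) and Id3 (0.52) (8 and 0 of 26, or 14 and 0, adjusted p = 0.00831). Immediate early genes with Junb (0.81) and Klf6 (0.59) (6 and 1 of 21, or 9 and 1, adjusted p = 0.021) and neural crest genes with Msx1 (0.53) and Ngfr (0.47) against Foxd3 (-0.52) (3 and 1 of 8, or 4 and 1, adjusted p = 0.0443) rose as lists.

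Lists that fell were heterochromatin, led by Cbx3, Ehmt2 and Dnmt3b (2 higher and 6 lower of 33, or 2 and 7 adjusted over the list alone, adjusted p = 0.000287), and p53 targets with Psrc1 (-0.55) and Trp53inp1 (-0.42) against Perp (0.39) (2 and 10 of 25, or 3 and 11, adjusted p = 0.00831). The neural progenitor list fell with Pax6, Sox1, Sox2 and Dll1 (0 and 7 of 24, or 0 and 8, median -0.28, adjusted p = 0.00835). Neuron genes fell (1 and 3 of 12, or 1 and 5, adjusted p = 0.0259), and so did the integrated stress response with Vldlr (-0.53) and Phgdh (-0.45) against Nupr1 (1.03) (3 and 9 of 34, or 5 and 12, adjusted p = 0.0443). When each of the 6 NPC libraries was left out in turn, epithelium, cholesterol synthesis, interferon, trophoblast, feeder and heterochromatin passed 6 of 6 times. The neural progenitor list passed 2 of 6 times and fell in all 6 (adjusted p from 0.0341 to 0.0894). Mesoderm and muscle passed 5 times, p53 targets 4, TGF-beta and BMP targets 3, neuron genes 1 and the other 3 lists 0 times. Cbx3, the target itself, and Ehmt2 are members of the heterochromatin list and carry GAGAGTT. Without genes that carry it the heterochromatin (adjusted p = 0.001495 by fry) and neural progenitor lists (0.00609) passed. The neuron (0.101), neural crest (0.197) and integrated stress response lists (0.43) did not. In the fit of all 10 libraries only the interferon list passed (adjusted p = 0.0352, and adjusted p = 0.228 with an estimated correlation).

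**Figure D4:**
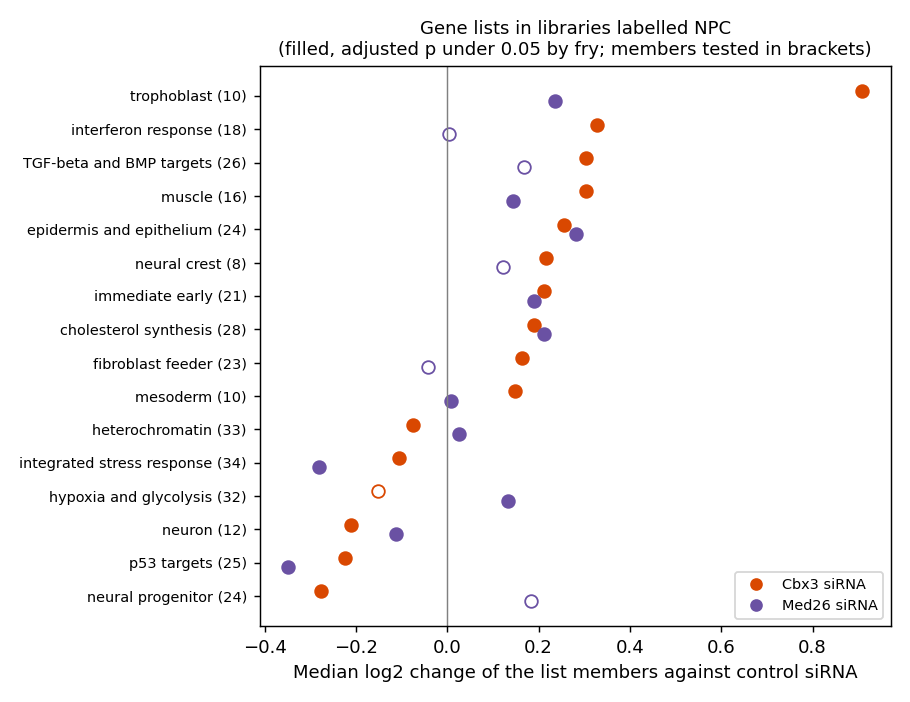
Median log2 change of each gene list after Cbx3 siRNA (orange) and Med26 siRNA (purple) in NPCs. Filled points passed adjusted p under 0.05 by fry in the 6 NPC libraries.

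Of the 16 lists that did not pass after Cbx3 siRNA in NPCs, those nearest the threshold were extracellular matrix (adjusted p = 0.0506), hypoxia and glycolysis (0.0517, although Pdk1, Bnip3 at -0.66 and Pfkl at -0.50 fell), glia (0.0668) and blood and endothelium (0.0939). The others were pluripotency (0.116, with Spp1 at 0.98 and Gdf3 at -0.50), germline (0.217), Notch pathway (0.239, although Hes6 fell by 0.79), cell cycle (0.321), Mediator (0.324), apoptosis (0.401), endoderm (0.416), transcription elongation (0.512), histone genes (0.569), oxidative phosphorylation (0.633), Wnt targets (0.766, although Sp5 rose by 0.99) and ribosomal proteins (0.786). None of the 31 Mediator genes tested passed.

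After the same knockdown in ESCs no gene passed in the fit of all 10 libraries, which sets each change against the wide spread of the ESC replicates and does not show that ESCs did not respond. In that fit limma called 0 genes after Cbx3 siRNA in ESCs, with 645 at unadjusted p under 0.05. The ESC genes named here beyond the fixed set are therefore given as values. The rule for named genes was applied in ESCs to the calls of the fit with the replicate number as a block, a use of it decided after the values were seen. Ehmt2 was 45.1 ± 14 RPKM in control and 14.4 ± 5.9 RPKM after Cbx3 siRNA (mean ± SD, n = 2, log2 change -1.60, adjusted p = 0.339). The autophagy receptor gene Calcoco2 was 3.40 ± 0.99 and 9.32 ± 1.1 RPKM (1.24, adjusted p = 0.262), and the Nodal antagonist gene Lefty2 24.2 ± 6.6 and 45.1 ± 7.4 RPKM (0.88, adjusted p = 0.391). Septin2 was 100.5 ± 7.7 and 56.3 ± 0.18 RPKM (-0.82, adjusted p = 0.243), and Erlin2 13.6 ± 2.5 and 6.86 ± 0.28 RPKM (-0.88, adjusted p = 0.262). Other large differences were Paip2b (0.88), Tnpo2 (0.81), Epha1 (-0.88), Rptor (-0.87) and Zfp369 (-0.80), and Lef1 was 4.32 and 1.52 RPKM. The transcripts of Ehmt2, Septin2, Erlin2, Rptor and Zfp369 carry GAGAGTT, and those of Calcoco2, Lefty2, Paip2b, Tnpo2, Epha1 and Lef1 do not.

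Of the fixed set, Pou5f1 (log2 change -0.32), Nanog (0.52), Pax6 (-0.31), Sox1 (-0.15), Nes (-0.29), Tubb3 (0.20), Acta2 (0.33), T (-0.05), Gata4 (0.12), Cbx1 (-0.07) and Cbx5 (-0.07) did not pass in ESCs in the fit of all 10 libraries (adjusted p of at least 0.966 for each). With the replicate number as a block, Nanog, Pou5f1 and Nes passed in ESCs, but not in the 4 ESC libraries alone with it. In these 4 libraries with the block, 16 of the 53 genes that the rule named for ESCs passed (limma). Among them were Cbx3, Ehmt2, Calcoco2, Lefty2, Septin2 and Erlin2. That fit leaves 1 residual degree of freedom, and the labels pair no libraries by number. None of the 31 lists passed in the fit of all 10 libraries either. The integrated stress response came closest (0 higher and 0 lower of 34, lower on balance, adjusted p = 0.0594), and the neural progenitor (adjusted p = 0.366) and epithelial lists (adjusted p = 0.871) stayed far from the threshold.

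Responses to Cbx3 siRNA in ESCs and NPCs nevertheless ran largely in parallel. Log2 changes in the cell types correlated at r = 0.564 over the 11956 tested genes, without any shared control library, and at 0.524 without the genes that carry GAGAGTT. Krt8, Lefty2 and Tnpo2 rose in NPCs and were higher after Cbx3 siRNA in ESCs (log2 changes in ESCs 0.80, 0.88 and 0.81). Ehmt2, Erlin2, Rptor and Dnmt3b fell in NPCs and were lower in ESCs (-1.60, -0.88, -0.87 and -0.45). The change of Pax6 was -0.98 in NPCs and -0.31 in ESCs, and that of Sox1 -0.71 and -0.15, differences that did not pass. No gene differed in its response between the cell types in the fit of all 10 libraries, where limma called 0 and 233 genes had unadjusted p under 0.05. That fit sets each difference against the wide spread of the ESC replicates, so 0 calls do not show equal responses. With the replicate number as a block 6 genes passed, and they are given below.

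**Figure D5:**
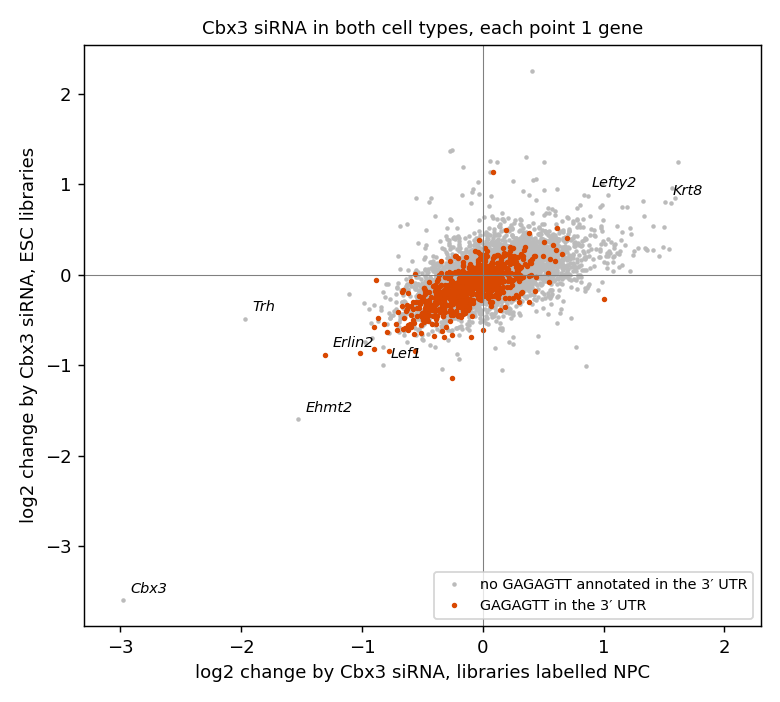
Log2 change of each gene after Cbx3 siRNA in NPCs (horizontal) and in ESCs (vertical). Genes with GAGAGTT in the 3' UTR are orange.

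Med26 siRNA in NPCs also raised Krt8 and Krt18, and it lowered Lefty1, Lefty2, Fgf8, Wnt8a and T. Lefty1 fell from 190 ± 10 to 74.4 ± 3.1 RPKM (log2 change -1.34, standard error 0.08, adjusted p = 0.00652 in the fit of all 10 libraries), while Cbx3 siRNA left it in place (-0.01, adjusted p = 0.939). Lefty2 (-0.89), Fgf8 (-1.42, adjusted p = 0.00756), Wnt8a (-1.16, adjusted p = 0.00843) and T (-0.76, adjusted p = 0.0133) fell in the 6 NPC libraries, and Krt8 (0.94, adjusted p = 0.0018), Krt18 (0.66, adjusted p = 0.0044) and Krt19 (1.15, adjusted p = 0.00224) rose. Pax6 (0.30, adjusted p = 0.0651) and Sox1 (0.30, adjusted p = 0.0696) did not pass, and Sox2 rose (0.33, adjusted p = 0.0249). Pou5f1 did not pass (-0.03, adjusted p = 0.792) and Nanog fell (-0.37, adjusted p = 0.0195). The largest rises were Acta1 (59.4 to 156 RPKM, 1.38), Dcaf12l1 (8.13 to 22.2 RPKM, 1.34), Ier3 (1.27), Anxa1 (1.23), Krt19, Lrp2 (38.1 to 83.0 RPKM, 1.10), Lgals3 (1.08) and Misp3 (1.05). Trh fell most (-2.18), followed by the histone genes H3f4 (94.1 to 27.7 RPKM, -1.73) and H2ac1 (55.9 to 17.2 RPKM, -1.64), then Enpp2 (-1.53), Cdca7l (21.6 to 6.86 RPKM, -1.53), Fgf8 and Lhpp (13.1 to 4.28 RPKM, -1.42). Over all genes searched, those with GACGGGC in the 3' UTR, the sequence with the lowest z after this siRNA, lay lower (z = -11.73). The Med26 transcript holds that sequence, and which of the genes named here carry it was not examined.

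In the fit of all 10 libraries 15 genes passed after Med26 siRNA, 3 higher and 12 lower, with 1385 at unadjusted p under 0.05. Among them were Dcaf12l1 and Cdca7l (adjusted p = 0.00626 for both), Lhpp (0.00406), Arhgap11a (-1.04, 0.012), Rce1 (-1.20, 0.0276), Cbx6 (-1.04, 0.0333), the activin receptor gene Acvr2b (-1.28, 0.0355) and Syap1 (0.0467). No gene passed without 1 of the NPC control or NPC Med26 siRNA libraries, 5 passed without either NPC Cbx3 siRNA library, 57 and 55 without ESC control replicate 1 and 2, and 51 and 49 without ESC Cbx3 siRNA replicate 1 and 2. The 6 NPC libraries gave 1597 genes, 825 higher and 772 lower (37 at least 2-fold), and 279 and 241 without NPC control replicate 1 and 2 and 165 and 320 without Med26 siRNA replicate 1 and 2.

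Of the 31 lists, 11 moved by fry after Med26 siRNA in the 6 NPC libraries. With an estimated correlation between genes none passed, at adjusted p = 0.176 for epithelium and cholesterol synthesis, 0.247 for p53 targets and 0.329 to 0.635 for the other 8. Epithelium (11 higher and 1 lower of 24, or 14 and 1 adjusted over the list alone) and cholesterol synthesis with Insig1 (1.04) and Msmo1 (0.74) (10 and 0 of 28, or 12 and 0) rose with adjusted p = 0.000673, and both passed 6 of 6 times when each NPC library was left out in turn. Mesoderm then passed 5 times, p53 targets 4, trophoblast and the integrated stress response 3, muscle 2, heterochromatin and neuron genes 1 and hypoxia and immediate early genes 0 times. Muscle (4 and 0 of 16, or 4 and 3, adjusted p = 0.00966), trophoblast (3 and 0 of 10, or 5 and 0, adjusted p = 0.00966), heterochromatin (4 and 1 of 33, both ways, adjusted p = 0.0182), hypoxia with Slc2a3 (0.81) and P4ha1 (0.61) (7 and 1 of 32, or 12 and 1, adjusted p = 0.0182) and immediate early genes (6 and 0 of 21, or 8 and 1, adjusted p = 0.0203) rose too. p53 targets fell with Phlda3 (-0.94), Cdkn1a (-0.84) and Bax (-0.43) (0 and 13 of 25, or 0 and 19, adjusted p = 0.00539). The integrated stress response fell with Pck2 (-0.84), Psat1 (-0.55) and Psph (-0.42) (1 and 15 of 34, or 5 and 19, adjusted p = 0.00966), as did mesoderm (0 and 3 of 10, both ways, median 0.01 and mean -0.22, adjusted p = 0.0114) and neuron genes (1 and 2 of 12, or 1 and 3, adjusted p = 0.0182). The Mediator list did not move (3 and 3 of 31, adjusted p = 0.826), with Med11 lower (-0.53) and Ccnc higher (0.46). Neural progenitor (3 and 1 of 24, adjusted p = 0.0969), TGF-beta and BMP (9 and 2 of 26, adjusted p = 0.0695) and ribosomal protein lists (0 and 10 of 55, adjusted p = 0.103) did not pass. Only the integrated stress response passed in the fit of all 10 libraries (adjusted p = 0.00272, and adjusted p = 0.201 with an estimated correlation).

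Set directly against each other, the knockdowns parted over Pax6, Sox1, T and Wnt8a. Compared with Med26 siRNA, Cbx3 siRNA left less Pax6 (log2 difference -1.28, adjusted p = 0.00112 in the 6 NPC libraries) and less Sox1 (-1.01, adjusted p = 0.0104 in the fit of all 10 libraries), and it left more T (1.14, adjusted p = 0.0295) and Wnt8a (1.78, adjusted p = 0.0173). Other large differences were Nupr1 (1.55) and Rce1 (1.49) upward and Septin2 (-1.45) and Trim2 (-1.12) downward. All 10 libraries gave 120 genes, 80 higher and 40 lower after Cbx3 siRNA, and the 6 NPC libraries gave 2185. Without Cbx3 siRNA replicate 1 or 2 the latter count was 971 or 698, and without Med26 siRNA replicate 1 or 2 it was 560 or 856. The count of 120 became 0 without any 1 of the Cbx3 or Med26 siRNA libraries of NPCs and 16 without either NPC control library, and 247, 245, 200 and 211 without ESC control replicate 1 and 2 and ESC Cbx3 siRNA replicate 1 and 2. Of the 31 lists, 10 differed in the 6 NPC libraries. Neural progenitor genes were lower as a list (0 higher and 10 lower of 24, or 1 and 18 adjusted over the list alone, adjusted p = 0.00692), as was heterochromatin (1 and 10 of 33, both ways, adjusted p = 0.000204), and interferon (8 and 0 of 18, or 12 and 0, adjusted p = 0.000739) and mesoderm genes (4 and 0 of 10, or 4 and 1, adjusted p = 0.000204) were higher. With an estimated correlation adjusted p was 0.205 for neural progenitor, heterochromatin and interferon lists and 0.375 for mesoderm. Without each NPC library in turn the neural progenitor list passed 3 of 6 times and the other 3 lists 6 of 6 times.

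Even so, 488 genes moved the same way after both siRNAs in NPCs. Of these, 333 rose (64.4 expected of independent lists) and 155 fell (41.1 expected). A further 56 moved in opposite directions (104.2 expected). Krt8, Krt18, Ier3 and Insig1 were among the genes raised by both, and Trh, Enpp2 and Dll1 (-0.47 after Med26 siRNA) among those lowered by both. Both comparisons use the same NPC control libraries. The covariance of the log2 changes was 0.0253, against 0.00529 in 100 simulations of unchanged groups set against those controls, which gave a mean of 0.02 shared genes. With no gene changed in the simulations almost none could be called. Their mean thus does not estimate how many of the 488 come from the shared controls. The correlation was 0.406, against 0.499 in the simulations, a difference that does not estimate a shared effect, and 0.239 and 0.271 with 1 control library for each side. Part of the overlap can come from the shared controls, and only 1 gene, Ier3, was called in both when all 10 libraries were fitted.

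Genes that separated the control groups were followed after Cbx3 siRNA in NPCs. The 228 genes at least 2-fold higher in ESC control had a median log2 change of 0.101, with 48 higher and 9 lower. Simulated unchanged groups that share the NPC controls, with each gene drawn independently, gave -0.003 to 0.023. Such ranges leave out variation shared between genes and can be too narrow. The observed median was 0.06 and 0.124 with the control libraries split between the comparisons. This set held 9 members of the fibroblast feeder list, of which 3 rose and 1 fell, and its median without them was 0.101 as well. Feeder genes outside that list were not told apart. Naive pluripotency genes, a list written after the data were examined, went both ways, 6 higher and 8 lower of 14, and limma called 0 of them. The 218 genes at least 2-fold higher in NPC control had a median of -0.001, inside the simulated range of -0.025 to 0.002, with 45 higher and 28 lower, and Pax6, Sox1 and Sox2 are not in this set. With the control libraries split between the comparisons, which left 79 and 69 such genes, the median was -0.029 and -0.061. After Med26 siRNA the medians were 0.121 and -0.115.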

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

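The difference between cell types and the fit with the replicate number as a block were both planned, and only the choice to list the calls of that fit here was made after the result was seen. In it 6 genes responded differently to Cbx3 siRNA in NPCs and ESCs, and this difference between groups is why they are listed. The log2 change was larger in NPCs than in ESCs for Ier3 (1.03 and 0.13, difference 0.90, adjusted p = 0.0287), Tgm1 (difference 0.98, adjusted p = 0.0287) and S100a6 (1.41 and 0.27, difference 1.14, adjusted p = 0.0368). Nanog was lower after Cbx3 siRNA in NPCs (-0.30) and higher in ESCs (0.52, difference -0.81, adjusted p = 0.0489), and it has 2 named pseudogene copies. Mir3064 (difference -1.63, adjusted p = 0.0368) and Mir677 (difference 1.86, adjusted p = 0.0287) are small RNA genes at or below 2.67 RPKM in every library. Without the block none of the 6 passed (adjusted p of at least 0.548). In NPC control Ier3 was 4.66 and 4.69 RPKM and after Cbx3 siRNA 10.8 and 10.4 RPKM, against 9.29, 9.58, 9.997 and 10.9 RPKM in the 4 ESC libraries.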

How the results depend on the processing

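Settings chosen only after the result was seen were the fits without genes that carry GAGAGTT, those without genes that have pseudogene copies, the median without feeder genes, and the use of the fit of the 6 NPC libraries as a basis. No reversal occurred among the named genes: 4103 values kept direction and side of the threshold, 386 gained the threshold and 64 lost it. Depth, 23.3 M to 63.8 M reads, limits low genes. By reads it was lowest in ESC Cbx3 siRNA replicate 2 (23.3 M). The number of fragments is not given. It would be lowest in ESC Cbx3 siRNA replicate 1 (16.8 M) if both reads of a pair were counted in all libraries but ESC replicate 2. For each change below the cause was not tested, except where fewer genes or libraries entered.

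The numbers 1 and 2 pair no samples by the labels. Deviations from the group mean of same-numbered libraries correlated at 0.892 between the ESC groups, at 0.423 to 0.461 among the NPC groups and at -0.069 to -0.038 across cell types, and same-numbered ESC libraries correlated at 0.991. With the replicate block, 1 for each cell type, the genes called became 2340 for Cbx3 siRNA in NPCs (1 without it), 813 for Cbx3 siRNA in ESCs (0 without it, and 55 in the 4 ESC libraries alone with the block), 2558 for Med26 siRNA (15 without it), 6 for the difference between cell types (0 without it), 3141 for Cbx3 against Med26 siRNA (120 without it) and 6912 for NPC against ESC control (1918 without it). The lists called became 17 (1 without it), 4 in ESCs (0 without it) and 10 for Med26 siRNA (1 without it), and the genes changed the same way by both siRNAs 761 (1 without it). Cbx3 itself passed with the block in NPCs (-2.98) and in ESCs (-3.59). Of the 813 ESC genes, 33.6% were higher (273 and 540), against 49% with median-ratio scaling and 45.7% with quantile normalization. The 4 ESC lists were hypoxia and glycolysis (adjusted p = 0.0125), the integrated stress response and p53 targets, all lower, and pluripotency, higher (adjusted p = 0.0339 for each, and adjusted p = 0.465 with an estimated correlation for all 4). Without genes that carry GAGAGTT only hypoxia and glycolysis passed of these (0.01832, against 0.05195 for the integrated stress response and p53 targets and 0.1025 for pluripotency). Between the 6 NPC libraries without a block and ESCs with it, 140 genes rose and 246 fell in both (21.3 and 28.8 expected), and 3 moved in opposite directions (56.7 expected). Among the 9855 genes left without those that carry GAGAGTT, 97 rose and 94 fell in both (14.3 and 8.6 expected), and 2 moved in opposite directions. The calls for Cbx3 siRNA in the 6 NPC libraries were then 806 higher and 385 lower, against 933 and 637 with all genes.

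The fit of the libraries of the cell type only called 1570 genes for Cbx3 siRNA in NPCs, 1597 for Med26 siRNA and 2185 between them, 15 and 11 lists for Cbx3 and Med26 siRNA, and 488 genes changed the same way. Cbx3 passed there too (-2.98).

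For Cbx3 siRNA in NPCs the count of 1 gene became 6 with a pseudocount of 0.1 or 0.5, 8 with no filter, 5 with a filter at 5 RPKM, 0 with median-ratio scaling, 6 with quantile normalization, 0 without a trend, 3 with robust moderation, 6 without genes that have copies, and 0 to 85 without 1 library. For Cbx3 siRNA in ESCs the count of 0 became 2 with no filter and 0 to 1 without 1 library. For Med26 siRNA the count of 15 became 23 without genes that have copies and 0 to 57 without 1 library. The difference between cell types went from 0 to 4 genes with no filter. Cbx3 against Med26 siRNA went from 120 to 36 genes at a 2-fold minimum and to 0 to 247 without 1 library, and NPC against ESC control from 1918 to 446 and to 185 to 2730.

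Without 1 library the log2 change of Cbx3 ranged from -3.07 to -2.88 in NPCs and from -4.56, which passed without ESC control replicate 1, to -2.62 in ESCs. That of Med26 ranged from -1.08 to -0.94 and lost its call without any 1 of the 6 NPC libraries (adjusted p from 0.0639 to 0.3671).

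The lists called for Cbx3 siRNA in NPCs went from 1 to 0 with a pseudocount of 0.1, 4 with 0.5, 2 with no filter, 0 with a filter at 5 RPKM, 2 with median-ratio scaling, 2 with quantile normalization, 12 with camera at a preset correlation, 0 with an estimated correlation and 0 to 5 without 1 library. In ESCs they went from 0 to 1 with a pseudocount of 0.1 or 0.5, 4 with camera at a preset correlation and 0 to 4 without 1 library. For Med26 siRNA they went from 1 to 3 with a filter at 5 RPKM, 3 with median-ratio scaling, 0 with quantile normalization, 5 with camera at a preset correlation, 0 with an estimated correlation and 1 to 4 without 1 library. The genes changed the same way by both siRNAs went from 1 to 4 with no filter, 0 with median-ratio scaling, 0 without a trend and 0 to 8 without 1 library.

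The median change after Cbx3 siRNA of genes higher in NPC control, -0.001, lay too close to 0 to keep a sign. It was -0.0347 and -0.0273 with a pseudocount of 0.1 and 0.5, 0.0051 with no filter, 0.0244 with a filter at 5 RPKM, -0.0133 with median-ratio scaling, -0.0306 with quantile normalization, 0.0251 with the replicate block, -0.0072 without a trend and with robust moderation, and -0.0926 to 0.0452 without 1 library. That of genes higher in ESC control, 0.101, stayed above 0, at 0.1461 with a pseudocount of 0.1, 0.0606 with quantile normalization, 0.0654 with the replicate block and 0.053 to 0.1437 without 1 library.

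In the 6 NPC libraries the count for Cbx3 siRNA of 1570 became 876 with no filter, 3495 with the replicate block, 58 at a 2-fold minimum and 390 to 1066 without 1 library. The count for Med26 siRNA of 1597 became 611, 3705, 37 and 165 to 1161 in the same order, and that for Cbx3 against Med26 siRNA of 2185 became 1325, 4234, 67 and 560 to 1692. The ESC count with the replicate block of 813 became 79 with no filter, 522 without a trend, 55 in the ESC libraries only, 19 at a 2-fold minimum and 396 without genes that carry GAGAGTT.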

Other observations

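Tests chosen only after the result was seen were those of how reads were counted, of pseudogene copies for the genes that have them, of ESC replicate 2 against the NPC state, and of the NPC state. The pluripotency genes of the NPC libraries parted by class. Lists of naive, primed and general pluripotency genes and of neural induction were written after Pou5f1 had been seen at its ESC level, and their genes were chosen after their values were seen. All 14 naive genes were lower in NPC control than in ESC control (median log2 difference -2.15), with Zfp42 at 14.3 and 16.0 RPKM against 79.6 and 58.6 RPKM. Of 12 primed genes 10 were higher, with Fgf5 at 5.12 and 4.62 RPKM against 0.156 and 0.797 RPKM, Pim2 at 81.5 and 73.0 RPKM against 6.85 and 31.8 RPKM, and Otx2 at 15.1 and 12.8 RPKM against 5.02 and 9.47 RPKM. The 9 general genes had a median difference of -0.006, and of 5 neural induction genes high enough to test, among 12, 4 were higher in NPC control (median 0.58).

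ESC-level Pou5f1 in the libraries labelled NPC was weighed against 3 explanations. Undifferentiated ESCs mixed into the cultures would carry naive genes in the same proportion as Pou5f1, if they kept both at ESC levels. The naive genes kept a median ratio of 0.14 (upper bootstrap bound 0.219) where Pou5f1 had 1.16, which argues against such a mixture. Their list was written after Pou5f1 had been seen, and the bound does not allow for that choice. Cells that kept Pou5f1 but lost naive genes, mixed with others, were not told apart. Swapped labels would put naive genes higher in NPC libraries, and their median difference was -2.15 (upper bound -1.31). A primed, epiblast-like state would raise primed genes and leave neural genes low, and the primed median was 1.01 (1.42 and 0.51 against ESC control replicate 1 and 2) with a median of 0.22 RPKM over the neural induction genes in NPC control, which is consistent with such a state. A start of neural induction beside it stays open, with 4 of 5 tested genes higher.

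The split of the ESC libraries by replicate number was weighed against technical and biological explanations. In ESC replicate 2 the share of 2-read values among low values was at most 0.345, against 0.61 to 0.646 in the other 8 libraries, which is consistent with 1 read counted per fragment there and both reads of a pair elsewhere. Genes with named pseudogene copies were higher in replicate 2 (median 0.634, matched lists -0.145 to 0.015), by 0.41, 0.926, 1.52 and 2.25 for 1, 2, 3 or 4, and 5 or more copies, so another treatment of reads with several matches may explain these genes. Without them and small RNA genes most of the split remained, with an SD of 0.524, against 0.575 with them and 0.171 in NPCs. Only pseudogenes named after their gene were counted, so this does not show how far reads shared with other copies enter the rest. GC content and length explained 4.0% of the variance (3.2% to 5.3%, 98.5% of genes). A replicate 2 culture nearer to the NPC state would not explain the whole split, since its correlations with the NPC difference were 0.037 and 0.078, but it may explain the pluripotency genes, with naive genes lower in replicate 2 (median -1.01 and -1.09 in the control and Cbx3 siRNA groups) and primed genes higher (0.728 and 0.677).

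The genes that fell after Cbx3 siRNA in both cell types, 246 called in the 6 NPC libraries without a block and in ESCs with it, were weighed against off-target matches of the siRNA and shared reads. Of 16021 sequences of 7 bases held by at least 50 genes in the 3' UTR, GAGAGTT ranked lowest by its weaker z. It went with lower values in NPCs (z = -15.09) and ESCs (-15.42) but not after Med26 siRNA (-1.24). In all, 18 sequences passed z under -4.66 in both cell types (29 in NPCs and 38 in ESCs). Of the 18, 11 passed after Med26 siRNA too. GAGAGTT was picked from these same changes, so its shares and medians are no separate test of it. Genes with 2 or more sites had medians of -0.107 in NPCs and -0.149 in ESCs, against 0.023 and -0.015 without a site, and Cbx3 itself holds 1 site, as 19.1% of transcripts do, which is consistent with a seed of the siRNA. Direct matches to GAGAGTT alone cannot be the whole cause, since only 48.8% of the lowered genes carry the sequence in the transcript (18.4% of others) and 31.4% in the 3' UTR. Shorter or shifted matches were not counted and the siRNA sequence is not given, so direct matches of other kinds stay open. Pseudogene copies and small RNA genes made up 5.7% of the lowered genes and 4.5% of all.

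After Med26 siRNA the sequence GACGGGC, held by 168 genes in the 3' UTR and by the Med26 transcript, went with lower values (z = -11.73, and -1.26 after Cbx3 siRNA). It was the lowest of 39 sequences that passed after this siRNA. The next, GCGCGGC, had z = -7.74, and -5.24 after Cbx3 siRNA. CGGCCCG (z = -5.88, and -5.94 after Cbx3 siRNA) is in the Med26 transcript too.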
